A study of Rattus norvegicus with 74 samples.

How the data were processed

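Liver RNA of Wistar Han rats was measured on 74 Affymetrix rat expression arrays in 15 groups, and near-identical arrays leave open whether each stands for an animal of its own. The deposited values are log2 expression per probe set, made with robust multi-array average (RMA) according to the submitters' processing notes, which give no version. Their range and their close array medians were checked and lie where RMA log2 values lie. The value distributions were close within each agent (mean SD of the sorted values 0.04 for BDE-47, 0.047 for DE-71, 0.025 for phenobarbital and 0.034 for PCB126) and wider over all arrays (0.07), so the agents look normalized separately, which no label states. For this reason each dose group was compared with the 0 mg/kg group of its own agent.

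The table holds 31099 probe sets. After 57 control probe sets were left out, 20826 probe sets had 1 gene symbol in the 2016 annotation of the array, 436 had several and 9780 had none. A gene was represented by the single-gene probe set with the highest mean over all arrays, which gave 14217 genes, 4525 of them with more than 1 probe set. Probe sets with several genes, among them a pair of Cyp2b genes, and probe sets with none entered no gene count. Genome positions are not given, because the files name no genome build. No filter on dim probe sets was used. Arrays have no counting depth, so the number of arrays per group limits the precision.

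Among the 656 pairs of arrays of the same agent, 4 pairs were nearly identical over the 300 most variable genes with a mean log2 value of at least 7 (root mean square difference below 0.3). A pair within the BDE-47 0 mg/kg group and a pair within the DE-71 15 mg/kg group were averaged, so that each counts as 1 sample, and 72 samples entered the fit. This departs from the plan, which had all 74 arrays as separate samples, and was decided after the values were seen. The remaining 2 pairs join a 15 and a 50 mg/kg array and stayed in the fit.

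A single linear model with 15 group means was fitted to all genes with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 57 residual and 5 prior degrees of freedom). Contrasts were each dose against 0 mg/kg of the same agent, 50 against 15 mg/kg, and the response to DE-71 minus the response to BDE-47 at each matched dose, as well as an F test over the 4 control groups. P values are two-sided and were adjusted by Benjamini and Hochberg within each contrast. A gene was called at an adjusted p below 0.05, and rose or fell refers to called genes. Fold changes are log2 differences of group means with their standard error (SE) or 95% confidence interval from limma, and group means are given with their SD. The median log2 fold change over all genes was at most 0.022 in size in any of these contrasts. The p values measure the spread between these samples, since nothing says that the animals come from separate litters. Sex is not given.

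The 28 gene lists held 575 entries, of which 496 were measured. They cover CAR and PXR targets, AhR targets, NRF2 targets, UGT and sulfotransferase conjugation, glutathione S-transferases, thyroid hormone handling and response, PPAR-alpha targets and fatty acid oxidation, cholesterol biosynthesis and uptake, fatty acid synthesis, bile acid synthesis and transport, glucose metabolism, cell cycle, the p53 and DNA damage response, the unfolded protein and integrated stress response, acute phase and inflammation, the circadian clock, fetal and neonatal liver, sex-biased adult liver genes, and Y-linked genes with Xist. The other lists hold markers of hepatocytes, of Kupffer cells and macrophages, of stellate cells and fibroblasts, of endothelium, of cholangiocytes, of lymphocytes, of neutrophils and myeloid precursors and of erythroid cells, as well as of pancreas and gut as contaminating tissue. A list shift was tested against all other genes with camera at a preset correlation of 0.01 and again with the correlation estimated per list, adjusted over the 28 lists. Beside it stand the members called over all genes and those called when adjusted over the list alone. Genes on the lists that were not measured were not analysed here.

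The groups, contrasts, tests, gene lists, alternatives and the rule for named genes were chosen before the data were examined. The rule names the 8 largest rises and the 8 largest falls among called genes with all treated samples on 1 side of the control mean, up to 4 called members per list by p (2 members where none was called), index genes of xenobiotic metabolism, thyroid hormone and fetal liver, and 5 genes per direction between agents or between 50 and 15 mg/kg. The text takes its named genes from this set and says where it departs from it.

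On simulated data, 50 genes were changed at each fold size among the 14217 genes, with the group sizes of the real samples. With the sizes of the BDE-47 50 mg/kg comparison the test recovered 34% of 1.25-fold, 76% of 1.5-fold, 98% of 2-fold and 100% of 4-fold changes, with 13 false calls. With those of DE-71 50 mg/kg it recovered 26%, 74%, 98% and 98%, with 10 false calls. With those of PCB126 250 mg/kg it recovered 24%, 76%, 94% and 100%, with 7 false calls. With no change simulated, 0 genes were called in each. With the CAR and PXR list raised 1.5-fold, its shift had an adjusted p of 1.3e-40 at the preset and 6.6e-18 at an estimated correlation, and of the 21 lists sharing no gene with it 0 were called either way. The noise was drawn independently for each gene, with the same SD in all groups. Correlated genes and arrays that stand apart were therefore not simulated, whereas the real cell cycle list had an estimated correlation of 0.67. The 0 false list calls hold only for independent genes.

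The alternatives were trend and robust moderation, every probe set, the mean of all probe sets of a gene, a filter on dim genes (above the median of 4.925 on at least 4 arrays, 10473 genes), quantile normalization again, centring of each array, array weights, a replicate block, a 1.5-fold threshold, only the arrays of the agents compared, and each sample left out in turn. Added after seeing the data were all 74 arrays as separate samples, leaving out the 4 arrays of the near-identical pairs between doses, and leaving out 4 arrays that stand apart (DE-71 0.1 mg/kg replicate 2, DE-71 50 mg/kg replicate 2, and PCB126 50 mg/kg replicates 2 and 5). The replicate numbers were checked as pairs, and among samples of 1 agent with the same number the residuals correlated above 0.1 in 6 of 27, 8 of 24, 3 of 15 and 14 of 30 pairs for BDE-47, DE-71, phenobarbital and PCB126, so the numbers were not taken to pair the samples.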

Results

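Liver gene expression was measured at postnatal day 22 in Wistar Han rats given BDE-47, a single tetrabrominated diphenyl ether congener, or DE-71, a commercial mixture of mainly tetra- and pentabrominated diphenyl ethers, by gavage. The labels give doses of 0, 0.1, 15 and 50 mg/kg for both, to dams from gestation day 6 to 21 and to pups from postnatal day 12 to 21. The series also holds rats given phenobarbital, a classic activator of the nuclear receptor CAR, at 0, 5 and 45. Further rats were given PCB126, a dioxin-like polychlorinated biphenyl and agonist of the aryl hydrocarbon receptor (AhR), at 0, 10, 50 and 250. The PCB126 doses are labelled mg/kg like the others, a unit that could not be checked. The schedule of the phenobarbital and PCB126 animals is not given separately. Each group has 5 arrays, except DE-71 50 mg/kg with 4, and array medians lay between 4.816 and 5.036 log2 units. The mean correlation of an array with the others of its group was 0.9783 to 0.9947, lowest for DE-71 50 mg/kg replicate 2. In the comparisons below, n counts samples after near-identical arrays of the same group were averaged, which leaves 4 for BDE-47 0 mg/kg and 4 for DE-71 15 mg/kg.

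**Figure D1:**
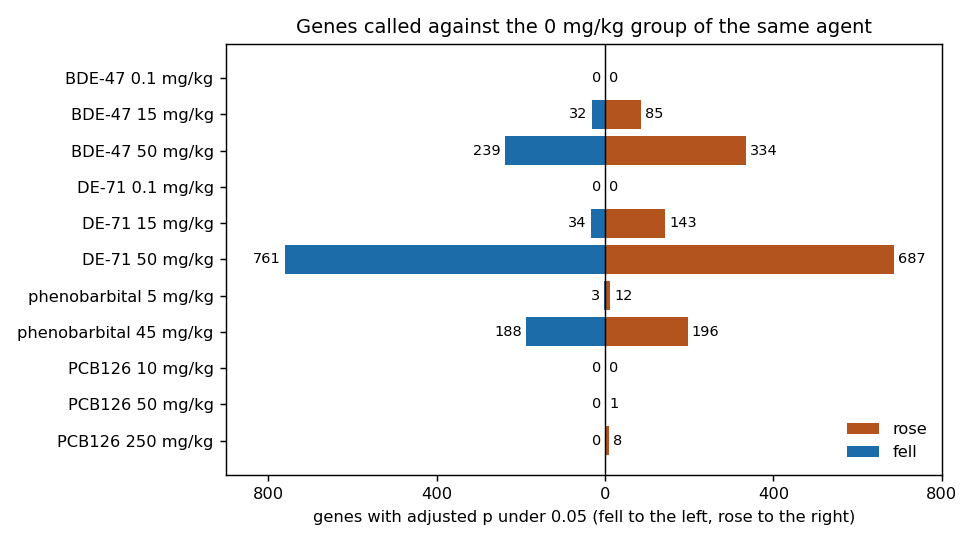
The bars give the number of genes that rose (to the right) or fell (to the left) at each dose against 0 mg/kg of the same agent, at an adjusted p below 0.05 in limma, of 14217 genes tested. DE-71 at 50 mg/kg has the longest bars with 687 genes that rose and 761 that fell (241 and 147 without replicate 2 of that group), while the lowest dose of BDE-47, DE-71 and PCB126 has 0.

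Phenobarbital at 45 mg/kg served as the reference for CAR activation (n = 5 against 5). Cyp2c7, a cytochrome P450, rose 73.5-fold (log2 fold change 6.2, 95% confidence interval 4.91 to 7.49, adjusted p = 1.3e-10), from 7.27 ± 0.45 to 13.47 ± 0.14 (SD), and the carboxylesterase gene Ces2c rose 14-fold (3.81, SE 0.24, adjusted p = 1.6e-19). Cltrn, encoding collectrin, rose by 4.94, the cytochrome P450 gene Cyp2a3 by 4.51, Cyp4a8 by 2.54, Meox2 by 2.33 and Retreg1 by 2.33 log2 units. Among the genes that fell were Scd, encoding stearoyl-CoA desaturase (-3.02, SE 0.7, adjusted p = 0.0058), Cyp7a1, the rate-limiting enzyme of bile acid synthesis (-2.31, SE 0.42, adjusted p = 0.00021), Cyp8b1, the sterol 12-alpha-hydroxylase of the same pathway (-1.88), Rprm (-2.07), Pcp4l1 (-1.98) and the chemokine gene Cxcl13 (-1.94). All 5 treated samples lay on the same side of the control mean for each of these, as their selection required.

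Of the 21 measured CAR and PXR targets, 16 rose and 0 fell at 45 mg/kg of phenobarbital (17 and 0 adjusted over the list alone, adjusted p = 9e-14 with an estimated correlation). Cyp3a23-3a1, a main drug-oxidizing P450, rose by 1.01 (adjusted p = 4e-10), Ugt2b1, which conjugates steroids and drugs with glucuronic acid, by 1.38, and Cyp2c6v1 by 0.88. Conjugation genes moved with them: 4 of 14 UGT and sulfotransferase genes rose and 1 fell (7 and 2 alone, adjusted p = 3.3e-06 with an estimated correlation), led by Ugt2b1 and by Sult1b1, a sulfotransferase of thyroid hormones (2.23). In addition, 7 of 19 glutathione S-transferase genes rose (9 and 1 fallen alone, adjusted p = 0.0049), among them Gstm3 (1) and Gsta4 (0.75). Of 23 NRF2 targets 4 rose (10 alone, adjusted p = 0.029 with an estimated correlation), including the export pump gene Abcc3 (1.26) and Ephx1, encoding microsomal epoxide hydrolase (1.36). Fatty acid synthesis had 1 gene risen and 5 fallen of 22 (1 and 6 alone, adjusted p = 0.43 with an estimated correlation), among them Fads2 (-1.58, adjusted p = 4.2e-08). Bile acid synthesis and transport had 2 risen and 5 fallen of 23 (2 and 7 alone, adjusted p = 0.43). In glucose metabolism 0 of 17 genes rose and 2 fell, Pc (-0.57) and Pygl (-0.41), with 0 and 2 alone and an adjusted p of 0.032 with an estimated correlation. Cyp1a1, the classic AhR target, stood at 1.11 (interval -0.03 to 2.24, adjusted p = 0.41), and Cyp1a2 at -0.57 (adjusted p = 0.032, not called in 8 of 10 leave-1-out fits, with -0.49 and 0.14 without 45 mg/kg replicate 5). In all, 384 genes were called, 196 risen and 188 fallen, 112 and 66 of them at least 1.5-fold, and 233 were called without phenobarbital 45 mg/kg replicate 5 and 739 with only the arrays of this comparison in the fit.

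At 5 mg/kg of phenobarbital 15 genes were called (n = 5 against 5), 12 risen and 3 fallen. Ces2c rose 3.18-fold (1.67, adjusted p = 1e-05), Ugt2b1 by 0.96 (adjusted p = 4.1e-07), Cyp2c6v1 by 0.64 (adjusted p = 4.1e-06), and C2h3orf80 fell (-1.27, adjusted p = 0.0014). Cyp2c7 rose 9.66-fold (3.27, adjusted p = 0.0097, but 2.94 and 0.051 without phenobarbital 5 mg/kg replicate 5). Of 20 genes of cholesterol biosynthesis and uptake, 3 rose over all genes and 18 when adjusted over the list alone (adjusted p = 0.0038 with an estimated correlation). Msmo1, of the sterol pathway, rose by 1.47, Idi1, isopentenyl diphosphate isomerase, by 1.44, and Sc5d, sterol-C5-desaturase, by 0.66. Each of the latter lost its call in some leave-1-out fits (highest adjusted p = 0.14 and 0.23 without 5 mg/kg replicate 4, and 0.13 without 0 mg/kg replicate 1). Of the CAR and PXR targets 4 rose (14 alone, adjusted p = 1.1e-09 with an estimated correlation), of the UGT and sulfotransferase genes 3 (6 alone, adjusted p = 8e-07) and of the glutathione S-transferases 1 (4 alone, adjusted p = 0.02). Of 20 genes with a sex bias in adult liver 1 rose, Cyp2c7 (4 alone, adjusted p = 0.015 with an estimated correlation). Between 5 genes (without 5 mg/kg replicate 2) and 24 (without replicate 3) were called with 1 sample left out, and 6 without 0 mg/kg replicate 1 or 5 mg/kg replicate 4. After quantile normalization again, 11 genes rose and 5 fell.

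PCB126 served as the reference for AhR activation, and at 250 it raised 8 genes, with 0 fallen (n = 5 against 5). Cyp1b1 rose 23.1-fold (4.53, SE 0.43, adjusted p = 4.2e-11), from 5.3 ± 0.1 to 9.83 ± 1.19, Cyp1a1 rose 18.9-fold (4.24, interval 3.1 to 5.37, adjusted p = 2.4e-06) and Cyp1a2 1.88-fold (0.91, SE 0.16, adjusted p = 0.0012), all cytochrome P450 genes under AhR control. The other genes were the quinone reductase gene Nqo1 (1.62), the chemokine gene Cxcl9 (1.53), Nfe2l2, which encodes the transcription factor NRF2 (0.76), Pkdcc (0.7) and the lysosomal acid phosphatase gene Acp2 (0.5, adjusted p = 0.00054). Of 14 AhR targets 5 rose (5 alone, adjusted p = 3.2e-08 with an estimated correlation), and of 23 NRF2 targets 1 rose (2 alone, adjusted p = 0.3). The CAR and PXR genes Cyp3a23-3a1 and Ugt2b1 stood at 0.02 and 0.1. Nqo1, Cxcl9, Nfe2l2 and Pkdcc lost their calls in at least 4 of 10 leave-1-out fits (adjusted p = 0.11, 0.23, 0.086 and 0.1 without 0 mg/kg replicate 5, where 4 genes were called), and 5 genes were called without 0 mg/kg replicate 3 or 4 or 250 mg/kg replicate 5. With a replicate block, Nqo1 (adjusted p = 0.082) and Nfe2l2 (0.054) were not called.

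The mean of Cyp1a1 was higher at each higher dose of PCB126, at 9.17 ± 0.98, 11.13 ± 0.68, 12.11 ± 0.4 and 13.41 ± 0.12 at 0, 10, 50 and 250 (n = 5 each). It was the only gene called at 50 (2.94, SE 0.57, adjusted p = 0.037, higher in 5 of 5 samples), and in 8 of 10 leave-1-out fits it was not (up to 0.44 without 0 mg/kg replicate 2), nor with a replicate block, which calls 0 genes. After quantile normalization again 1 gene rose and 1 fell. At 10, limma called 0 genes, with 379 at an unadjusted p below 0.05, and Cyp1a1 stood at 1.96 (interval 0.83 to 3.1, unadjusted p = 0.001, adjusted p = 1). Cholesterol biosynthesis at 50 had 0 members called over all genes and 3 fallen when adjusted over the list alone (adjusted p = 2e-14 at the preset and 0.18 with an estimated correlation).

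**Figure D2:**
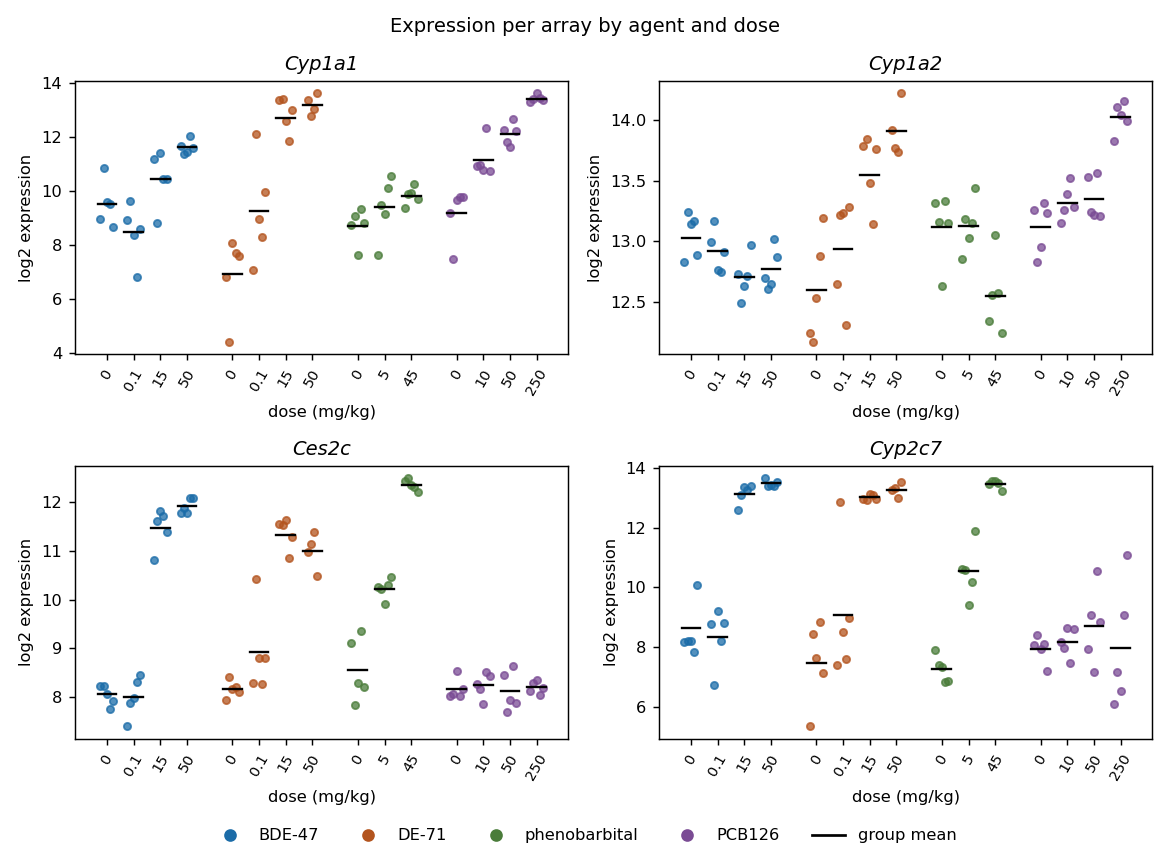
Each point is an array and each line a group mean of log2 expression, by dose in mg/kg and agent, for Cyp1a1, Cyp1a2, Ces2c and Cyp2c7. The means of Cyp1a1 rise from 9.17 at 0 to 13.41 at 250 of PCB126 and from 6.91 at 0 to 13.19 at 50 mg/kg of DE-71, and a single array of DE-71 0.1 mg/kg lies at 12.1, above the others of its group.

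BDE-47 was compared with its controls to see which genes a single congener moves. At 50 mg/kg (n = 5 against 4) Cyp2c7 rose 29.2-fold (4.87, interval 3.5 to 6.24, adjusted p = 1e-06), Cyp2a3 22.7-fold (4.51, SE 0.56), Cltrn 19.4-fold (4.28, SE 0.4) and Ces2c 14.5-fold (3.86, SE 0.25, adjusted p = 1.5e-18), from 8.06 ± 0.18 to 11.92 ± 0.16. Sult1e1, the estrogen sulfotransferase gene, rose by 3.27, Gpx2, encoding a glutathione peroxidase, by 2.65, Zdhhc2 by 2.53 and Sult1b1 by 2.27. The largest falls were in Abcg8 (-2.94, SE 0.43, adjusted p = 2.3e-06) and Abcg5 (-2.66, SE 0.42), whose products together carry sterols into bile, with Abcg8 at 3.99 ± 0.35 against 6.93 ± 0.31. Further falls were in Pcp4l1 (-2.34), Cxcl13 (-2.1), the taurine transporter gene Slc6a6 (-2.05), Qpct (-1.96), Mmd2 (-1.93) and A2m, encoding alpha-2-macroglobulin (-1.8, adjusted p = 0.00019). In each of these genes all 5 treated samples lay on the same side of the control mean, as their selection required.

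Of the 21 CAR and PXR targets, 16 rose at 50 mg/kg of BDE-47 (18 alone, 0 fallen, adjusted p = 5.7e-11 with an estimated correlation), among them Ces2c, Aldh1a1, an enzyme of retinoic acid synthesis (1.88), Ugt2b1 (1.02), Cyp3a23-3a1 (0.89, adjusted p = 1.3e-07) and Cyp2c6v1 (0.76). Of 14 UGT and sulfotransferase genes 6 rose (6 and 2 fallen alone, adjusted p = 0.00021), including Ugt2a1 (1.12). Of 19 glutathione S-transferase genes 7 rose (10 and 1 fallen alone, adjusted p = 0.0054), including Gstt3 (0.99) and Mgst2 (0.76). Of 23 NRF2 targets 7 rose (10 alone, adjusted p = 0.043 with an estimated correlation), such as Abcc3 (1.72), Ephx1 (1.52) and the malic enzyme gene Me1 (1.86). Of the 14 AhR targets 2 rose, Cyp1a1 and the methyltransferase gene Inmt (1.59), which also rose with phenobarbital at 45 mg/kg (2.15). Adjusted over the list alone, 3 rose and 1 fell (adjusted p = 0.47 with an estimated correlation). Cyp1a1 rose by 2.11 (interval 0.9 to 3.31, adjusted p = 0.029), a call that ended in 6 of 9 leave-1-out fits (1.93 and 0.11 without 0 mg/kg replicate 1), and Cyp1a2 stood at -0.26 (interval -0.6 to 0.08). Bile acid synthesis and transport had 2 risen and 2 fallen of 23 genes (3 and 5 alone, adjusted p = 0.85), the export pump gene Abcc2 (1.09) beside Abcc3, Abcg5 and Abcg8, and glucose metabolism had 2 fallen of 17 (adjusted p = 0.058). Tkfc fell (-1.07, adjusted p = 0.00022) and Lpl, encoding lipoprotein lipase, rose (1.96, adjusted p = 2.6e-05). In all, 573 genes were called, 334 risen and 239 fallen, 154 and 104 of them at least 1.5-fold, and 359 were called without the averaged 0 mg/kg replicates 3 and 4.

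At 15 mg/kg of BDE-47, 117 genes were called (n = 5 against 4), 85 risen and 32 fallen, with Cyp2c7 (4.52, SE 0.68, adjusted p = 1.3e-05), Cyp2a3 (3.82), Cltrn (3.49), Ces2c (3.41, SE 0.25, adjusted p = 5.9e-16) and Meox2 (2) among the largest rises. Abcg8 fell (-2.36, adjusted p = 5e-04), and Abcg5 (-1.79, adjusted p = 0.014) was not called without the averaged 0 mg/kg replicates 3 and 4 (-1.81, 0.06). The CAR and PXR targets had 12 risen and 0 fallen (15 alone, adjusted p = 8.2e-11 with an estimated correlation), with Aldh1a1 at 1.54, Ugt2b1 at 1.05 and Cyp3a23-3a1 at 0.76. The UGT and sulfotransferase genes had 5 risen (5 alone, adjusted p = 4.2e-05). NRF2 targets had 3 risen (6 alone, adjusted p = 0.13 with an estimated correlation), of which Abcc3 stood at 1.53, and the glutathione S-transferases 2 (5 alone, adjusted p = 0.067). Cyp1a1 stood at 0.95 (interval -0.26 to 2.15, adjusted p = 0.59). The count was 44 without the averaged 0 mg/kg replicates 3 and 4 and 56 without 15 mg/kg replicate 3. At 0.1 mg/kg limma called 0 genes, with 457 at an unadjusted p below 0.05, and Cyp1a1 stood at -1.04 (interval -2.24 to 0.16). Between 50 and 15 mg/kg limma called 0 genes (427 unadjusted), and 5 without 15 mg/kg replicate 3 and 2 without 50 mg/kg replicate 3, the pair of near-identical arrays with these labels. There Cyp1a1 stood at 1.16 (interval 0.02 to 2.29) and Ugt2b1 at -0.04 (interval -0.27 to 0.2).

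DE-71 was tested in the same way, and at 50 mg/kg the AhR target Cyp1a1 rose most, 77.6-fold (6.28, interval 5.07 to 7.48, adjusted p = 1e-11, n = 4 against 5), from 6.91 ± 1.47 to 13.19 ± 0.37. Cyp2c7 rose 55.8-fold (5.8, SE 0.68, adjusted p = 7.3e-09), Sult1e1 45.3-fold (5.5, adjusted p = 2.6e-09), Cltrn 14.9-fold (3.9), Cyp2a3 14.3-fold (3.84), the hydroxysteroid sulfotransferase gene Sult2a2 12.9-fold (3.68) and Snx10 8.08-fold (3.01). Falls were led by Cxcl13 (-3.09, adjusted p = 5.1e-07), A2m (-2.56), Slc6a6 (-2.19), Rprm (-2.13), Cyp17a1, the 17-alpha-hydroxylase of steroid synthesis (-2.04), Qpct (-2) and Qsox1 (-1.74). In each of these all 4 treated samples lay on the same side of the control mean, as their selection required. Rup2 (3.41) and Abcg8 (-1.81) were also called, but not without 50 mg/kg replicate 2 (2.45 with an adjusted p of 0.19, and -1.57 with 0.05). That array had the lowest correlation with its group. Of 1448 genes called, 687 risen and 761 fallen, 388 were called without it, 241 risen and 147 fallen, and 380 genes are in both sets. With only the arrays of this comparison in the fit 350 were called. Without it Cyp1a1 rose by 6.22 (adjusted p = 5.9e-10) and Cyp2c7 by 5.8 (adjusted p = 2e-07).

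Of 14 AhR targets 7 rose and 2 fell at 50 mg/kg of DE-71 (7 and 2 alone, adjusted p = 0.00077 with an estimated correlation, 5 and 1 without replicate 2). Cyp1a2 rose by 1.31 (SE 0.17, adjusted p = 7e-08), Cyp1b1 by 2.58 (7.61 ± 2.36 against 5.02 ± 0.13, higher in 3 of 4 samples), and Fmo1, a flavin monooxygenase gene, fell (-1.54). The CAR and PXR targets had 16 risen and 0 fallen (17 and 1 alone, adjusted p = 3.8e-08, 16 and 0 without replicate 2), with Ces2c at 2.85, Aldh1a1 at 1.4, Ugt2b1 at 1.22 and Cyp3a23-3a1 at 0.98. NRF2 targets had 14 of 23 risen (15 alone, adjusted p = 0.012, 9 without replicate 2), among them Gsta4 (1.39, adjusted p = 8.7e-13), Abcc3 (1.75), Ephx1 (1.74) and the aldo-keto reductase gene Akr7a3 (2.79). The glutathione S-transferases had 9 of 19 risen (11 and 1 fallen alone, adjusted p = 0.004, 8 risen without replicate 2). The UGT and sulfotransferase genes had 7 risen and 2 fallen of 14 (7 and 2 alone, adjusted p = 0.0021, 5 and 0 without replicate 2). Glucose metabolism had 0 risen and 5 fallen of 17 (0 and 5 alone, adjusted p = 0.014 with an estimated correlation, 0 and 2 without replicate 2). These include the glycogen phosphorylase gene Pygl (-0.55) and Fbp1, fructose bisphosphatase of gluconeogenesis (-0.44). Fatty acid synthesis had 1 risen and 5 fallen of 22 (adjusted p = 0.59) and bile acid synthesis and transport 3 and 5 of 23 (adjusted p = 0.56), with 1 and 1, and 3 and 2, without replicate 2. Slc27a5, which activates bile acids, fell (-0.71, adjusted p = 3.9e-06), and Abcc2 rose (1.13).

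At 15 mg/kg of DE-71, 177 genes were called (n = 4 against 5), 143 risen and 34 fallen, and 43 with only the arrays of this comparison in the fit. Cyp1a1 rose 54.9-fold (5.78, interval 4.58 to 6.98, adjusted p = 5.1e-10), Cyp2c7 46.8-fold (5.55, SE 0.68), Cyp2a3 12.7-fold (3.67), Cltrn 9.99-fold (3.32), Ces2c 9.02-fold (3.17, adjusted p = 1.5e-14) and Retreg1 5.18-fold (2.37). Rprm (-1.48), Lcmt1, a methyltransferase gene (-1.32, adjusted p = 3.9e-06), and Tkfc (-0.99) fell. Each lay on the same side of the control mean in 4 of 4 samples, as the rule requires of the largest falls. The CAR and PXR targets had 13 risen (16 alone, adjusted p = 1.2e-12 with an estimated correlation), including Ugt2b1 (1.09) and Cyp3a23-3a1 (0.95). The AhR targets had 3 risen (4 alone, adjusted p = 3.7e-05), with Cyp1a2 at 0.95 (SE 0.17). NRF2 targets had 6 risen (9 alone, adjusted p = 0.0077), with Gsta4 at 0.82 and Ephx1 at 1.77. The glutathione S-transferases had 4 risen (8 alone, adjusted p = 0.0019), with Gstm1 at 0.87, and the UGT and sulfotransferase genes 5 (7 and 1 fallen alone, adjusted p = 2.7e-05). The count was 101 without the averaged 15 mg/kg replicates 1 and 2, 112 without 15 mg/kg replicate 4, and 109 and 110 without 0 mg/kg replicates 3 and 4.

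At 0.1 mg/kg of DE-71 limma called 0 genes (n = 5 against 5), with 908 at an unadjusted p below 0.05, and 1 without 0 mg/kg replicate 3 or 0.1 mg/kg replicate 1. Cyp1a1 stood at 2.36 (interval 1.22 to 3.49, unadjusted p = 1e-04, adjusted p = 0.43), Ces2c at 0.75 and Ugt2b1 at 0.42. Replicate 2 of this group held Cyp1a1 at 12.1, Cyp2c7 at 12.88 and Ces2c at 10.42, against 7.05 to 9.96, 7.39 to 8.96 and 8.26 to 8.8 in the other 4. The CAR and PXR targets had 0 called over all genes and 2 risen adjusted over the list alone (adjusted p = 0.014 with an estimated correlation). How much of this list shift rests on replicate 2 was not tested, as the list was not fitted again without it. Between 50 and 15 mg/kg of DE-71, 28 genes were called, 19 higher and 9 lower at 50. Higher were the aldehyde dehydrogenase gene Aldh3a1 (1.55, adjusted p = 0.0063), the protease inhibitor gene Slpi (1.57), St6galnac2 (1.53), Ttc39a (1.45) and Oas1a, of the interferon response (1.19). Lower were A2m (-1.48, adjusted p = 0.048), Cyp17a1 (-1.39), Trim2 (-1.07), Steap3 (-1.03) and Usf3 (-0.94). This count was 1 without 50 mg/kg replicate 2, 2 without 15 mg/kg replicate 3, 17 without 15 mg/kg replicate 4 and 18 without the averaged 15 mg/kg replicates 1 and 2. It was 48 without 50 mg/kg replicate 5, 531 without 50 mg/kg replicate 4, which is nearly identical to 15 mg/kg replicate 5, and 5 with a replicate block. With only the arrays of this comparison in the fit, limma called 0.

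The single congener and the mixture were compared at matched doses through the difference of their responses, DE-71 minus BDE-47. At 15 mg/kg 2 genes differed, both AhR targets: Cyp1a1 responded more to DE-71 by 4.83 log2 units (interval 3.13 to 6.54, adjusted p = 0.0056) and Cyp1a2 by 1.27 (interval 0.79 to 1.74, adjusted p = 0.011). Each response was taken from the controls of its own agent. Cyp1a1 stood there at 9.5 ± 0.96 for BDE-47 and 6.91 ± 1.47 for DE-71. These levels were compared only within the F test over the 4 control groups. Its treated means for BDE-47 and DE-71 were 10.45 ± 1.03 and 12.69 ± 0.66 at 15 mg/kg. They were 11.61 ± 0.26 and 13.19 ± 0.37 at 50 mg/kg. Part of the Cyp1a1 difference between agents thus lies in the lower DE-71 controls. At 50 mg/kg 17 genes differed, with a positive difference in 15 and a negative one in 2. Positive differences were those of Cyp1a1 (4.17, interval 2.47 to 5.88, adjusted p = 0.017), Cyp1a2 (1.57, interval 1.1 to 2.05, adjusted p = 0.00015), the antigen presentation genes RT1-Ba (2.37, interval 1.32 to 3.42) and Cd74 (2.2, interval 1.22 to 3.17), the chemokine gene Ccl5 (1.98, adjusted p = 0.0079) and St6galnac2 (1.69), among others. The responses of Cd74 were opposite in sign, -1.29 with BDE-47 and 0.9 with DE-71, as were those of RT1-Ba (-1.06 and 1.31) and Ccl5 (-0.82 and 1.16). Cd74 was not called by limma with DE-71, however, and its call with BDE-47 was lost without BDE-47 0 mg/kg replicate 2. Of 12 Kupffer cell and macrophage markers, 1 differed over all genes (C1qc at 0.94, but 0.82 with an adjusted p of 0.22 without DE-71 50 mg/kg replicate 2) and 8 adjusted over the list alone, with positive differences (adjusted p = 0.16 with an estimated correlation). Those of Rybp (-0.8, interval -1.11 to -0.48) and Abhd11 (-0.52, interval -0.76 to -0.28) were negative, as Rybp stood at -0.77 with DE-71 and 0.03 with BDE-47, and Abhd11 at -0.27 and 0.25. Of the 21 CAR and PXR targets 0 differed over all genes by limma at either dose, and adjusted over the list alone 0 did at 15 and 1 at 50 mg/kg, with a negative difference. The list had an adjusted p of 0.76 at 15 and 0.81 at 50 mg/kg with an estimated correlation. Its members went both ways at 50 mg/kg, with Ces2c at -1.01 (adjusted p = 0.29), Aldh1a1 at -0.48 (0.42), Cyp3a23-3a1 at 0.09 (interval -0.24 to 0.42) and Ugt2b1 at 0.21 (interval -0.15 to 0.56). At 0.1 mg/kg limma called 0 genes (644 unadjusted), with Cyp1a1 at 3.4 (interval 1.75 to 5.06, adjusted p = 0.48).

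These counts moved with the fit and with single samples. With only the arrays of the agents compared, 0 genes differed at 15 and 6 at 50 mg/kg. Without DE-71 50 mg/kg replicate 2 the genes differing at 50 mg/kg were Cyp1a2 (1.57, adjusted p = 6e-04) and Prf1, the perforin gene (1.2, adjusted p = 0.037), while Cyp1a1 stood at 4.12 (0.054), Ccl5 at 1.86 (0.054), RT1-Ba at 2.24 (0.15), Cd74 at 2.07 (0.15), St6galnac2 at 1.05 (0.36), Rybp at -0.66 (0.11) and Abhd11 at -0.57 (0.054). The count was 10, 5 and 29 without BDE-47 0 mg/kg replicates 1, 2 and 5, and 11, 11, 37 and 6 without BDE-47 50 mg/kg replicates 1, 3, 4 and 5. It was 8 and 11 without DE-71 0 mg/kg replicates 1 and 5, 27 and 71 without DE-71 50 mg/kg replicates 3 and 4, and 40 with a replicate block. The 2 genes at 15 mg/kg were 0 without BDE-47 0 mg/kg replicate 2. They were 1 without the averaged BDE-47 0 mg/kg replicates 3 and 4, without DE-71 0 mg/kg replicate 1 or 2, without the averaged DE-71 15 mg/kg replicates 1 and 2 or without DE-71 15 mg/kg replicate 5. For the AhR list the test of the difference gave an adjusted p of 0.053 at 15 and 0.032 at 50 mg/kg with an estimated correlation.

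**Figure D3:**
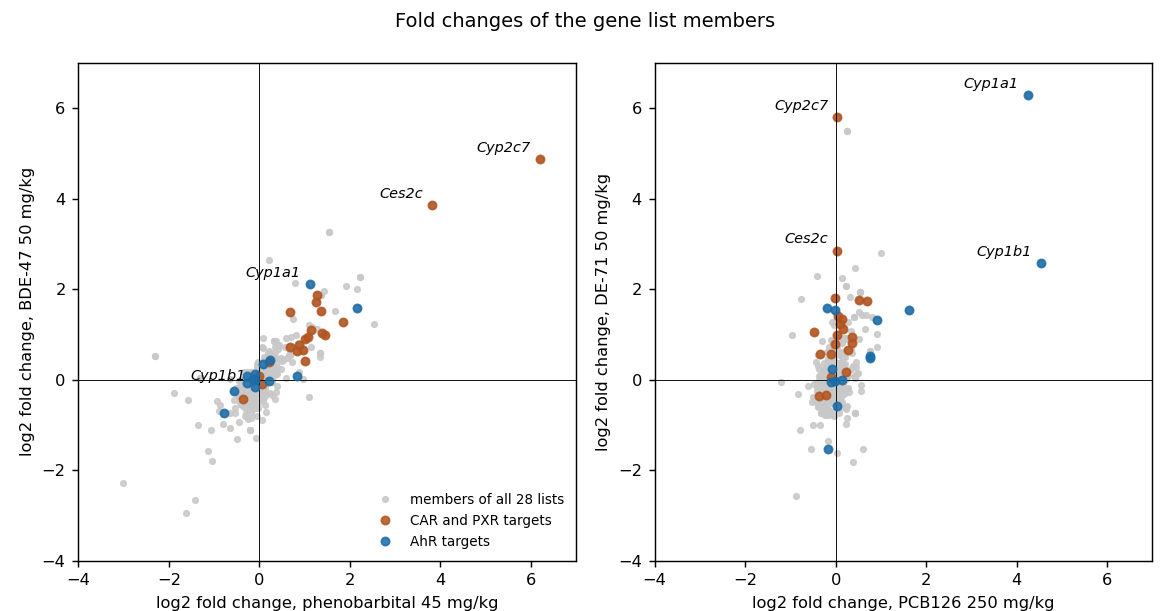
Each point is a gene of the 28 lists, at its log2 fold change for phenobarbital 45 mg/kg (x) and BDE-47 50 mg/kg (y) on the left, and for PCB126 250 mg/kg (x) and DE-71 50 mg/kg (y) on the right. Cyp2c7 lies at 6.2 and 4.87 on the left among the CAR and PXR targets, and Cyp1a1 lies at 4.24 and 6.28 on the right among the AhR targets.

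The brominated agents were set beside both references across all 14217 genes, which are not independent replicates, and each agent has controls of its own. BDE-47 50 and phenobarbital 45 mg/kg raised 130 genes in common, where 4.6 would be shared by chance, and lowered 75 (3.2 by chance), with 0 in opposite directions. Cyp2c7, Ces2c, Cltrn and Cyp2a3 are in the former set and Cxcl13 and Pcp4l1 in the latter. The fold changes correlated with r = 0.66 (rho = 0.49), and 375 of the 384 phenobarbital genes had the same sign with BDE-47. DE-71 50 and phenobarbital 45 mg/kg raised 127 genes in common (9.5 by chance) and lowered 85 (10.1), with 1 opposite and r = 0.54 (rho = 0.3). With PCB126 at 250, DE-71 shared 7 of the 8 raised genes (0.4 by chance, r = 0.3, rho = 0.17), with 0 opposite. BDE-47 shared 1 (0.2 by chance, r = 0.13, rho = 0.11), which is Cyp1a1, with 1 opposite, Pkdcc (-0.53 with BDE-47), and 4 of the 8 genes had the same sign, against 7 with DE-71. These correlations have jackknife SDs over the samples of 0.17 and 0.11 and were not tested against each other. That of DE-71 was 0.168 without PCB126 250 mg/kg replicate 5, and that of BDE-47 was 0.09 without PCB126 0 mg/kg replicate 1. BDE-47 and DE-71 at 50 mg/kg raised 194 genes in common (16.1 by chance) and lowered 92 (12.8), with 0 opposite (r = 0.55, rho = 0.32). At 15 mg/kg they raised 58 (0.9) and lowered 8 (0.1), with 0 opposite and r = 0.51 (rho = 0.27). All overlaps of DE-71 50 mg/kg, and their chance values, rest on 687 risen and 761 fallen genes. Without replicate 2 of that group these were 241 and 147, and the overlaps were not counted again. The correlation of DE-71 with phenobarbital was 0.58 without that array.

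Genes of thyroid hormone handling and response formed a list of their own, as glucuronidation and sulfation also clear thyroid hormone. Of its 20 genes, 2 rose at BDE-47 50 mg/kg, 3 rose at DE-71 15 mg/kg, 3 rose and 2 fell at DE-71 50 mg/kg (3 and 1 without replicate 2) and 2 rose and 1 fell at phenobarbital 45 mg/kg, with adjusted p of 0.67, 0.34, 0.81 and 0.84 with an estimated correlation. Sult1b1 and Me1 rose in each of these. The transporter gene Slco1b2 rose with DE-71 (0.58 at 15 mg/kg, adjusted p = 0.003), and the fall with phenobarbital was that of Cyp7a1, a shared member. At DE-71 15 mg/kg Sult1b1 (1.46) and Me1 (1.49) lost their calls in 3 and 6 of 9 leave-1-out fits (up to 0.11 without 15 mg/kg replicate 4 and 0.26 without the averaged replicates 1 and 2). At phenobarbital 45 mg/kg Me1 lost its call in 5 of 10 (up to 0.11 without 45 mg/kg replicate 5). The deiodinase gene Dio1 stood at 0.18 with BDE-47 50 mg/kg, -0.05 with DE-71 50 mg/kg and -0.27 with phenobarbital 45 mg/kg, and Ttr, encoding the thyroxine carrier transthyretin, at -0.01, -0.03 and -0.05. Neither was called. Serpina7, encoding thyroxine-binding globulin, fell at DE-71 50 mg/kg (-1.53, adjusted p = 0.01), but stood at -0.94 (0.14) without 50 mg/kg replicate 5. Of 28 PPAR-alpha targets and genes of fatty acid oxidation, at most 2 rose and 2 fell, at DE-71 50 mg/kg (2 and 0 without replicate 2, smallest adjusted p of any dose group 0.53), and Cyp4a8 rose there by 1.79 (adjusted p = 0.0047).

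The 4 control groups differed in 5207 genes by an F test in limma (6745 unadjusted, 1715 with a replicate block, 2955 with the dim filter, 869 at least 1.5-fold apart), so no other test set levels of 1 agent against those of another. As each agent forms its own set of arrays, a difference between the sets of animals and one of array processing cannot be separated.

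**Figure D4:**
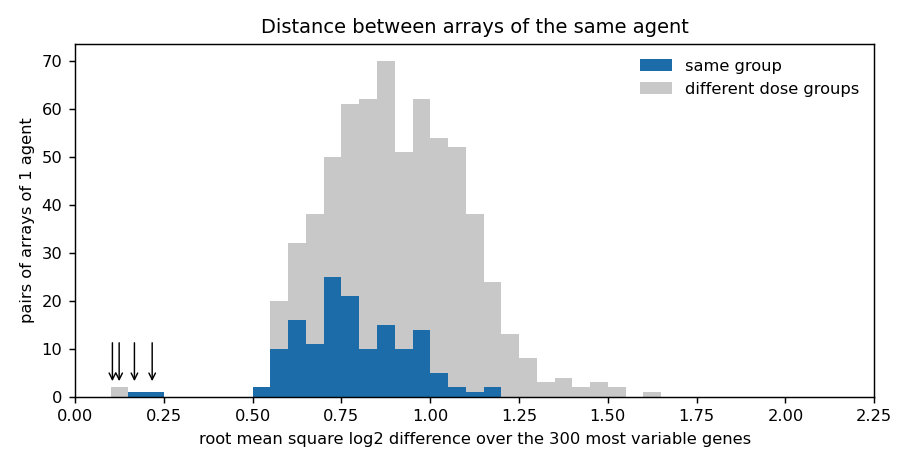
The bars count the 656 pairs of arrays of the same agent by the root mean square log2 difference over the 300 most variable genes, for pairs of the same group and of different dose groups. Arrows mark 4 pairs at 0.105 to 0.217, while the other pairs start at 0.535.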

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

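The root mean square comparisons of array pairs, the swap test, the held-out samples and the spread of the share in other arrays were chosen only after the results they concern were seen, whereas the other tests of the 3 patterns below were written down before.

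In 2 pairs of nearly identical arrays the labels give different doses: BDE-47 15 mg/kg replicate 3 with 50 mg/kg replicate 3, and DE-71 15 mg/kg replicate 5 with 50 mg/kg replicate 4. The same RNA on both arrays is supported over the 700 next most variable genes, not used to choose the pairs, where they differ by 0.092 and 0.116, the closest other of 45 dose pairs by 0.293 and the near-identical arrays of 1 group by 0.153 to 0.184. A like response to both doses is argued against over the same genes, since the closest of 144 other pairs of arrays of 1 group, which share a dose, differs by 0.215. A first test, the correlation of deviations from the other arrays of each group, gave 0.31 and 0.41 against 0.35 in the highest other pair and decides nothing, because the deviations were taken from different dose groups, so that 1 RNA need not give like deviations. Which label is right stays open, and no biological explanation was tested beyond a like response.

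DE-71 50 mg/kg replicate 2 sets much of the count of that group, with 388 genes called without it against 1448. A lower share of hepatocyte RNA cannot be told apart from the rest. Hepatocyte markers had a median difference of -0.31 from the other arrays (quartiles -0.61 and 0.01), the direction of a lower share. Of the 8 marker lists of other cell types 3 have medians below the other arrays, endothelial markers by -0.28 (upper quartile -0.02). The neutrophil list lies above by 0.88. The test set beforehand asked all 8 to rise and counted at least 3 medians below as the opposite outcome. The result met the latter, so this test went against a lower share. As a lower hepatocyte share need not raise all 8 lists, that outcome does not decide. RNA of neutrophils cannot be told apart from the rest, because that list has 6 measured members and an interquartile range of 0.26 to 2.4 about its median of 0.88. A larger response of the same genes cannot be told apart either, because its slope of 1.32 on the mean response of the other arrays, over 388 genes called without it, exceeds 1 by less than the range of the others' slopes (0.67 to 1.2). The lowest of these is that of replicate 4, the array nearly identical to one of 15 mg/kg, which also enters the mean. All of these explanations stay open.

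DE-71 0.1 mg/kg replicate 2 had induced genes near the level of the higher doses, among them Cyp3a23-3a1 at 13.41 (12.98 to 13.02 in the other 4). A swap with a DE-71 15 or 50 mg/kg array of the series is argued against. Of the DE-71 15 and 50 mg/kg arrays, 0 lay on the control side for most of the 177 genes called at 15 mg/kg. Samples held out of the calls did so for at most 36.7%. The replicate numbers of DE-71 50 mg/kg start at 2, so a swap with an array outside the series could not be tested. Swaps with arrays of the other agents were not tested. The 0.1 mg/kg array had a slope of 0.83 on the 15 mg/kg response, below the 0.89 to 1.13 of the 15 mg/kg arrays, but these chose the genes. Held out in turn they have slopes of 0.78 to 1.05 against 0.75 to 0.91 on the same genes. They have 8.9 to 36.7% of genes on the control side against 29.7 to 46.1%. On each matched gene set the 0.1 mg/kg array had the lower slope (0.77 against 0.78 at the closest) and the higher share. As the ranges overlap, RNA of an animal given a higher dose cannot be told apart from the rest. Nor can induced RNA mixed into a 0.1 mg/kg sample, whose linear share has a median of 0.47 and an interquartile range of 0.67 over the 143 risen genes, because that range is 0.6 to 0.82 in the 15 and 0.48 to 1.66 in the 50 mg/kg arrays, so the bound of 0.2 set beforehand was too narrow. Both stay open, and an intermediate dose was not tested.

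A sample stood apart from the others of its group in 14 of 165 gene and group combinations, that of Cyp3a23-3a1 above included, where chance alone would give 8.2. In PCB126 50 mg/kg replicate 2, Xist, which female cells express, was at 9.89 (3.12 to 3.39 in the others) and the Y-linked gene Eif2s3y at 2.45 (8.67 to 9.47 in the others), unlike all other arrays. Uty, also Y-linked, was at 9.07 there, above the 7.58 to 8.21 of the others. Xist and Eif2s3y thus lay as in a female and Uty did not. Whether the Uty probe set reads only the Y-linked gene was not tested, so the sex of this array stays open. Smaller departures were Xist at 3.26 in phenobarbital 45 mg/kg replicate 3 and Eif2s3y at 8.22 in phenobarbital 0 mg/kg replicate 1. Cyp1a1 was low at 7.48 in PCB126 0 mg/kg replicate 2 and high at 12.33 in PCB126 10 mg/kg replicate 4, and Cyp1a2 was low at 12.63 in phenobarbital 0 mg/kg replicate 3. Cyp3a9, a dim probe set, was high at 3.68 in PCB126 250 mg/kg replicate 5 and at 4 in BDE-47 15 mg/kg replicate 4, and Ugt2b1 was low at 13.2 in phenobarbital 5 mg/kg replicate 2. Dio1 was low at 6.61 in the averaged BDE-47 0 mg/kg replicates 3 and 4 and high at 7.7 in BDE-47 0.1 mg/kg replicate 1, and Thrsp was low at 8.92 in DE-71 0 mg/kg replicate 2.

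The responses to BDE-47 and DE-71 differed by the test of the difference itself in 2 genes at 15 mg/kg, Cyp1a1 (4.83) and Cyp1a2 (1.27), and in 17 at 50 mg/kg. Of the latter, Cyp1a1 (4.17), RT1-Ba (2.37), Cd74 (2.2), Ccl5 (1.98), St6galnac2 (1.69), Rybp (-0.8) and Abhd11 (-0.52) are those the rule for named genes selects by size. Part of the Cyp1a1 difference lies in the lower DE-71 controls, as given above. Without DE-71 50 mg/kg replicate 2 the 17 became 2, and with only the arrays of the agents compared there were 0 at 15 and 6 at 50 mg/kg.

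A probe set matching 2 Cyp2b genes, the classic targets of CAR, entered no gene count. It was raised by 2.08 and 2.17 at BDE-47 15 and 50 mg/kg, by 2.25 and 2.23 at DE-71 15 and 50 mg/kg and by 1.13 and 1.97 at phenobarbital 5 and 45 mg/kg, and stood at -0.36 at PCB126 250 mg/kg (adjusted p = 0.87). Which of these genes gave the signal cannot be read from it.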

How the results depend on the processing

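Treating all 74 arrays as separate samples, leaving out the 4 near-identical arrays between doses and leaving out the 4 arrays that stand apart were chosen only after the results were seen, while the other alternatives were planned. None of the named genes called against their controls reversed under the probe mean, quantile normalization, the replicate block or any leave-1-out fit. Named genes without such a call were not followed in this way. The cause was not tested where a value moved, except where fewer samples or genes are tested. Array number and the spread between samples limit these counts, and the test on simulated data recovered at least 94% of 2-fold, 74% to 76% of 1.5-fold and 24% to 34% of the smallest simulated changes.

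With single samples left out, the called genes ranged from 5 to 24 at phenobarbital 5 mg/kg, 233 to 356 at phenobarbital 45 mg/kg, 0 to 1 at PCB126 50 mg/kg and 4 to 8 at PCB126 250 mg/kg. They ranged from 44 to 116 at BDE-47 15 mg/kg, 359 to 615 at BDE-47 50 mg/kg, 0 to 1 at DE-71 0.1 mg/kg, 101 to 191 at DE-71 15 mg/kg and 388 to 1963 at DE-71 50 mg/kg. Between 50 and 15 mg/kg they ranged from 0 to 5 for BDE-47 and 1 to 531 for DE-71, and between the agents from 0 to 2 at 15 and 2 to 71 at 50 mg/kg. Genes differing among controls ranged from 4534 to 5180. The correlations ranged from 0.63 to 0.67 for BDE-47 and 0.494 to 0.58 for DE-71 with phenobarbital. They ranged from 0.09 to 0.184 for BDE-47 with PCB126 and 0.168 to 0.347 for DE-71 with PCB126. Of the named genes, 21 of 34 at BDE-47 15, 15 of 58 at BDE-47 50, 15 of 40 at DE-71 15, 27 of 76 at DE-71 50, 9 of 13 at phenobarbital 5, 12 of 48 at phenobarbital 45, 1 of 1 at PCB126 50 and 4 of 8 at PCB126 250 mg/kg lost the call in at least 1 such fit.

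With trend and robust moderation PCB126 50 mg/kg had 0 genes. Counting every probe set gave 0 at PCB126 50 mg/kg, 4 differing between agents at 15 mg/kg, 13126 among controls and r = 0.597 for BDE-47 with phenobarbital. The dim filter gave 2955 among controls, and quantile normalization again gave 2 at PCB126 50 mg/kg. Array weights gave 191 at BDE-47 15, 971 at BDE-47 50, 489 at DE-71 50, 59 at phenobarbital 5, 836 at phenobarbital 45 and 4 at PCB126 50 mg/kg. They also gave 8 and 4 between 50 and 15 mg/kg of BDE-47 and DE-71, and 6 between agents at 50 mg/kg. With a replicate block PCB126 50 mg/kg had 0, DE-71 50 against 15 mg/kg 5, the agents at 50 mg/kg 40 and the controls 1715. A 1.5-fold threshold left 76 at BDE-47 15, 258 at BDE-47 50, 105 at DE-71 15, 513 at DE-71 50 and 178 at phenobarbital 45 mg/kg, and 869 among controls. With only the arrays of the comparison there were 43 at DE-71 15, 350 at DE-71 50 and 739 at phenobarbital 45 mg/kg. There were 0 for DE-71 50 against 15 mg/kg, and 0 and 6 between agents at 15 and 50 mg/kg.

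Over only the genes called in either comparison, r was 0.825 for BDE-47 and 0.72 for DE-71 with phenobarbital and 0.526 for DE-71 with PCB126. The rank correlations with phenobarbital were 0.486 and 0.302. All 74 arrays as separate samples gave 339 at BDE-47 15, 991 at BDE-47 50 and 307 at DE-71 15 mg/kg. They also gave 54 for DE-71 50 against 15 mg/kg and 38 between agents at 50 mg/kg. Without the arrays shared between dose groups there were 61 at BDE-47 15 and 0 at PCB126 50 mg/kg. There were 9 and 305 between 50 and 15 mg/kg of BDE-47 and DE-71, and 1 and 57 between agents at 15 and 50 mg/kg. Without the 4 arrays that stand apart there were 1 at BDE-47 0.1, 450 at DE-71 50 and 0 at PCB126 50 mg/kg. There were 2 and 1 between 50 and 15 mg/kg of BDE-47 and DE-71, and 9 between agents at 50 mg/kg.

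Of 75 list shifts called at the preset correlation over the 11 comparisons with controls, 30 were called with an estimated correlation, 68 with the dim filter and 73 with the replicate block, and 0 reversed. Scaling moved the median fold change of all genes to at most 0.033 with quantile normalization again and 0.037 with centring.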

Other observations

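The counts of other splits of the samples were chosen only after the results were seen, and the gene lists below were planned.

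Of 12 Kupffer cell and macrophage markers, 6 fell at BDE-47 50 mg/kg (9 adjusted over the list alone, n = 5 against 4, adjusted p = 4.4e-08 at the preset and 0.058 with an estimated correlation). They included the complement genes C1qc (-0.73, adjusted p = 0.00056) and C1qa (-0.6), the Kupffer cell receptor gene Clec4f (-0.8, adjusted p = 0.0098) and the macrophage growth factor receptor gene Csf1r (-0.68). With single samples left out, C1qa (0.054 without 50 mg/kg replicate 5) and Csf1r (0.07 without 0 mg/kg replicate 2) lost their calls. At 15 mg/kg C1qc fell (-0.64, adjusted p = 0.011, 0.079 without 0 mg/kg replicate 2), and 8 of the 12 fell when adjusted over the list alone (adjusted p = 0.14 with an estimated correlation). At 0.1 mg/kg 0 were called by limma, but the list median was already -0.23 (camera adjusted p = 0.00072 at the preset and 0.96 with an estimated correlation). All doses were compared with the same 0 mg/kg samples, so high marker levels in these controls were not separated from a fall with treatment. With DE-71 at 50 mg/kg 0 of the 12 were called by limma. The difference between the agents was called for 1 marker over all genes, C1qc (0.94, adjusted p = 0.03, but 0.82 and 0.22 without DE-71 50 mg/kg replicate 2), and for 8 over the list alone (adjusted p = 0.16 with an estimated correlation). At BDE-47 50 mg/kg 1 of 17 lymphocyte markers fell, Cd74 (-1.29, adjusted p = 0.017, 0.19 without 0 mg/kg replicate 2). Further, 1 of 18 stellate cell and fibroblast markers fell, Ecm1 (-0.73, 0.22 without 50 mg/kg replicate 1). Of the 18 hepatocyte markers 1 rose and 2 fell (1 and 6 alone, adjusted p = 0.67). Epcam, a marker of cholangiocytes and progenitors, rose at BDE-47 50 mg/kg (1.35, adjusted p = 6.4e-06) and DE-71 50 mg/kg (1.28), the only one of 7 cholangiocyte markers called in any dose group.

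Among genes with a sex bias in adult liver, 5 of 20 rose at BDE-47 50 mg/kg (6 alone, adjusted p = 0.043 with an estimated correlation), 5 at DE-71 50 mg/kg (8 and 1 fallen alone, adjusted p = 0.067) and 4, with 1 fallen, at phenobarbital 45 mg/kg (6 and 1 alone, adjusted p = 0.27). At phenobarbital 5 mg/kg 1 rose, Cyp2c7 (adjusted p = 0.051 without 5 mg/kg replicate 5), and 4 alone (adjusted p = 0.015 for the list), and at 15 mg/kg 3 rose with BDE-47 (5 alone, adjusted p = 0.067) and 3 with DE-71 (5 alone, adjusted p = 0.11). The genes risen at the highest doses included genes expressed more in male rats, such as Cyp2c11 (2, 1.82 and 2.16), beside Cyp2c7, expressed more in females, which is also in the CAR and PXR list. Of 16 p53 and DNA damage genes, 2 rose and 1 fell at BDE-47 50 mg/kg (5 and 2 alone, adjusted p = 0.27). There Mdm2, a p53 target, rose by 0.72 (adjusted p = 0.00056). At DE-71 50 mg/kg 4 rose and 2 fell, with 0 and 0 without replicate 2 (Mdm2 0.57, then 0.27 with an adjusted p of 0.3). Acute phase genes had 4 risen and 5 fallen of 27 at DE-71 50 mg/kg (5 and 7 alone, adjusted p = 0.81, 3 and 2 without replicate 2). Lcn2 (1.5) and Cxcl10 (0.89) rose and A2m and Itih3 (-0.34) fell. At BDE-47 50 mg/kg A2m and Serpina3n (-0.73, adjusted p = 0.00085) fell. At DE-71 50 mg/kg 1 of 18 hepatocyte markers rose and 5 fell (1 and 7 alone, adjusted p = 0.17, 1 and 3 without replicate 2), among them Cyp2e1 (-0.46, adjusted p = 1.4e-05) and the urea cycle gene Cps1 (-0.47).

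Smaller changes in the remaining lists at DE-71 50 mg/kg were 2 risen and 3 fallen of 18 stellate cell and fibroblast markers, 0 and 2 of 12 endothelial markers and 1 and 2 of 17 circadian clock genes. There were 1 and 0 of 14 erythroid markers and 1 and 0 of 17 lymphocyte markers. Each of these lists had 0 and 0 without replicate 2. Of 17 fetal and neonatal liver genes, Igf2bp3 fell with DE-71 (-0.73 at 15 and -0.75 at 50 mg/kg) and Lpl rose in 4 of the 11 dose groups, at DE-71 15 mg/kg with an adjusted p of 0.12 without replicate 3. Afp, encoding alpha-fetoprotein, stood at -0.88 and -0.78 at 50 mg/kg of BDE-47 and DE-71 (adjusted p = 0.19 and 0.17). Of 33 cell cycle genes Ccnd1, encoding cyclin D1, fell at BDE-47 50 mg/kg (-1.31, adjusted p = 0.015, 0.079 without 50 mg/kg replicate 1) and DE-71 50 mg/kg (-1.35, adjusted p = 0.0064, 0.087 without replicate 2). At most 1 of 24 unfolded protein and integrated stress response genes was called in any dose group (smallest adjusted p of the list 0.43). By limma, 0 of 6 neutrophil and myeloid precursor markers, 0 of 14 pancreas and gut markers and 0 of 3 Y-linked genes with Xist were called in any dose group (smallest adjusted p with an estimated correlation 0.56, 0.25 and 0.48).

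Other splits of the samples were drawn, 100 per comparison with the real one included. A count as large was found in 1 split, the real one, for BDE-47 15 mg/kg (117, highest other 68), BDE-47 50 mg/kg (573, 296), DE-71 15 mg/kg (177, 122), phenobarbital 5 mg/kg (15, 3) and phenobarbital 45 mg/kg (384, 53). The same held for the controls (5207, 1516) and the differences between agents at 15 (2, 0) and 50 mg/kg (17, 1). For these, chance in the division of single samples can be excluded, with no adjustment over the comparisons, except for the differences between agents. There only treated samples changed places, after subtraction of each agent's control mean, so chance in the controls was not covered. As litters are not given, none of the splits covers chance between litters. The list shifts pooled over all 11 dose groups with an estimated correlation gave 30, and the highest other split 21. Those splits were drawn separately per dose group, while doses of an agent share controls, so they do not exclude chance. Taken per dose group with an estimated correlation, a count of lists as large was found in 2 to 4 splits for BDE-47 50, DE-71 15 and 50 and phenobarbital 5 and 45 mg/kg. It was found in 18 for BDE-47 15, 17 for DE-71 0.1 and 18 for PCB126 250 mg/kg, where chance cannot be excluded for the list counts, and the other dose groups had 0 lists. At a share of 2 to 4 in 100 chance can be excluded only narrowly, with no adjustment over the comparisons, for DE-71 50 mg/kg with 4 splits (1448, 2228). The same applies to PCB126 50 mg/kg with 4 (1, 4), a single gene that 8 of 10 leave-1-out fits do not call, and to PCB126 250 mg/kg with 2 (8, 484). For the pooled list shifts at the preset correlation, 4 splits gave as many (75, 79), and the median other split gave 52. These were pooled in the same way and do not exclude chance. Per dose group, a preset count of lists as large was found in 4 splits for phenobarbital 45 mg/kg and in 9 to 73 for the other dose groups, so there chance cannot be excluded for the latter. It cannot be excluded for DE-71 50 against 15 mg/kg either, where 5 of 35 splits called as many (28, 197). For counts of 0 by limma the splits decide nothing, since all 100 reach 0 whatever the samples: BDE-47 0.1 mg/kg (highest other 162), DE-71 0.1 mg/kg (775), PCB126 10 mg/kg (2), BDE-47 50 against 15 mg/kg (2) and the difference between agents at 0.1 mg/kg (0). For BDE-47 0.1, DE-71 0.1, DE-71 50 against 15 and PCB126 250 mg/kg the highest other split called far more genes than the real one. For DE-71 50 mg/kg 1 split called 2228. This points to a structure of the samples within these groups, which was not tested and was not separated from the single arrays that stand apart, such as DE-71 0.1 mg/kg replicate 2 and DE-71 50 mg/kg replicate 2.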
